A study of Drosophila melanogaster with 2 samples.

How the data were processed

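The samples were 2 ChIP-seq libraries from whole Drosophila melanogaster embryos (0 to 14 h, mixed sex) that express a GFP fusion of CG17802, sheared by sonication to 200 to 800 bp. The labels number them biological replicates 1 and 2 and give both the same fly line. They form 1 group, so no comparison between conditions was made. Replicate numbers were taken from the labels. One label field describes the libraries as an input control. The antibody field names CG17802, the assay field says transcription factor ChIP-seq, and a separate experiment is listed as control. The accompanying file descriptions derive the peak lists from these alignments together with a control.

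Per the labels and the accompanying file descriptions, the authors made 4 peak lists on the dm6 genome: 1 for each replicate, 1 from both replicates pooled, and an optimal set thresholded for reproducibility between replicates (IDR). The first 3 hold peaks and background as input for that step. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The signal of each peak is the value the authors deposited in the narrowPeak signal column; its scale is not stated. It was used to rank peaks and to compare medians of peaks within a list, so ratios and differences of signal are in the authors' units and are not fold enrichments. Signals of the replicates' lists were also correlated across peaks. The −log10 q-value column, as deposited by the authors, reached a ceiling of 3.66 in the pooled list, shared by 2303 peaks, and was used only to rank peaks in an alternative. The deposited column of other values, the summit offset, gave summit positions; an offset outside its own interval (1 peak in replicate 1, 4 in replicate 2) was replaced by the midpoint. Every thresholded peak was among the 3535 highest of the pooled list. In the thresholded set 33 peaks repeated an interval already listed, and all were counted as separate peaks. The most common width was 330 bp in the pooled list (95.7% of peaks), so most widths carry no information on the bound segment. Read counts were not used here and the depth of each library is unknown, so no precision could be derived from depth.

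Coordinates are 1-based on dm6 and all peaks ended inside its reference sequences. Genes and TSSs came from Ensembl release 115, with transposable elements left out (18164 genes, of which 13945 are protein-coding, on the main arms). Start and end were identical in the RefSeq annotation for 13965 of 13967 protein-coding genes matched by symbol. A promoter peak has its summit within 500 bp of a TSS. For counts of promoters, TSSs with gaps of up to 500 bp were merged, giving 17629. Centromere-proximal segments were fixed as 2L above 22 Mb, 2R below 6 Mb, 3L above 23 Mb, 3R below 4.5 Mb and X above 22.5 Mb.

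Replicate overlap and the promoter share were set against 1000 circular shifts along each arm (200 for alternative settings, 20 for annotation classes). Region classes, gene lists and motifs used two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05, over 8 classes, 28 lists and 16 motifs. Motif windows spanned 100 bp on each side of the summit, with flanks centred 500 bp away. The alternative with windows of 250 bp also moved the flanks farther from the summit. The 8-mers were ranked on 2L and 3L and the 5 leading ones that share fewer than 5 bases in a row retested on 2R, 3R, X and 4. Median signals were compared with permutation tests (100000 resamples). Intervals of shares are Wilson 95% intervals and, like the limit set by a count of 0 (3 counts), cover counting error only. Peaks, promoters and genes are the units of these tests, not samples, so the p-values describe this peak set and not variation between embryos.

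Genes were named by a rule fixed before the data were examined: the 25 thresholded peaks with the highest signal and the gene of the nearest TSS, Nnk itself, and up to 4 bound members with the highest signal of each list with at least 5 members. All fixed motifs and the 5 discovered 8-mers were named too. Alternatives set at the same time covered the number of top peaks, the overlap rule, promoter distances of 200 and 1000 bp, 1 TSS per gene, stricter thresholds, each replicate's list alone, other backgrounds, and other windows and k-mer lengths. Some were added after seeing the data and are named as such.

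The tests were tried on simulated data. A planted promoter share of 48.6% in 3000 peaks was recovered as 48.6%, a planted 46.4% of bound promoters on chromosome 4 among 17629 promoters as 46.4%, and all 5 raised lists of 28 were called. Both planted shares were counted from the same simulated peaks as the estimates, so their agreement was largely built in and checks the code only. A planted 8-mer in 5.47% of 1500 windows was found, as was 1 planted motif of 16. Of 20 simulated sets with nothing planted, 0 gave a call for promoter share, region classes, gene lists and 8-mers, and 1 did for motifs. Those sets bound promoters and genes independently and drew all windows from random genome positions. They do not cover genes that share a peak, or summits that differ from their flanks in composition. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 20.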

Results

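Binding of CG17802, a zinc finger protein of the ZAD family (gene symbol Nnk, FBgn0038549), was profiled by ChIP-seq in whole Drosophila melanogaster embryos of mixed sex aged 0 to 14 h. The embryos came from a transgenic line that carries a GFP fusion at the C terminus of the protein. There was 1 group of 2 biological replicates from a single fly line, and no second condition. Each replicate's list and the pooled list held 30000 peaks, most of them background by design, and the set that passed the authors' reproducibility threshold held 3535. Read depth per library was unknown. The signal of a peak is the authors' value and ranks peaks within a list. It ran from 109.8 to 22497 in the thresholded set, with a median of 186.5. One label field calls these libraries an input control, while the antibody field names CG17802, the assay field names transcription factor ChIP-seq and a separate control is listed.

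Of the 25 strongest peaks, 24 lay at promoters, defined as a summit within 500 bp of an annotated transcription start site (TSS). The highest peak (2L:16325288-16326296, signal 22497) was 204 bp from a TSS of cact, the inhibitor of the Dorsal transcription factor. Next came CG14903 (signal 20958), Dis3, a nuclease of the RNA exosome (19982), lncRNA:CR43130 (17833), WASp, an activator of actin assembly (14618), fl(2)d, a component of the RNA methylation machinery (14438), and Rheb, the GTPase that activates TOR (14187). The 8th was at lncRNA:CR44209 (12937). The 9th (4:696572-697426, signal 12347) was the only one of the top 25 outside a promoter. It was intergenic, 763 bp from the TSS of ey, a Pax6 gene of eye development. Peaks at CG10465, gw, Top2, PlexA, CG41099, Gyf and chic, which encodes profilin, ranked 10, 11, 13, 14, 15, 16 and 17. Several peaks lay within 500 bp of TSSs of more than 1 gene. Rank 3 was shared by Dis3 and Rrp5, rank 4 by lncRNA:CR43130 and aqz, rank 6 by fl(2)d and CG13339, rank 7 by Rheb and CG2931, and rank 8 by lncRNA:CR44209, Cyt-b5 and Drat. Rank 12 was shared by CG13994 and ND-51, rank 18 by mRpL16 and trr, rank 19 by CG12025 and HBS1, and rank 20 by BORCS6 and klar. Ranks 21 to 25 were CG40045, IleRS-m, UQCR-11, vtd, which encodes a cohesin subunit, with lncRNA:CR45181, and CG4627 with AQP. Of the 25, 4 lay on chromosome 4, 5 in centromere-proximal segments and 16 elsewhere. None ranked below 27 in replicate 1 or 26 in replicate 2.

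Both replicates placed their strong peaks at the same sites. Of the 3535 highest peaks of each list, 72.3% overlapped one of the other list's by at least 1 bp, against a mean of 1.60% and a maximum of 4.47% over n = 1000 circular shifts along the arms (p = 0.001, the smallest that these shifts can give). The share was 88.0% for the top 25 peaks, 90.5% for the top 100 and 84.1% for the top 500. The thresholded set was itself chosen by the authors for reproducibility between replicates, so its presence in both lists is no independent measure of it. A peak was listed in both replicates for 3470 of the 3535 thresholded peaks (98.2%). Across those peaks the signals had a Spearman rho of 0.734 and a Pearson r of 0.893 on the log10 scale, and peaks are not independent replicates.

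**Figure D1:**
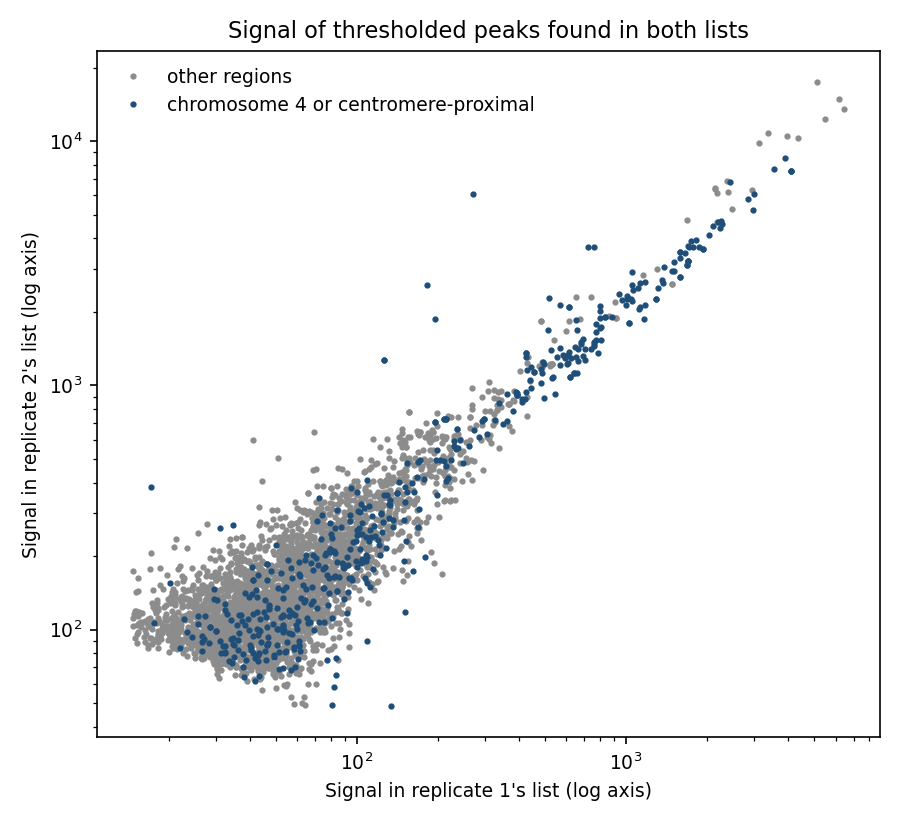
Signal in replicate 1's list (x, log axis) against replicate 2's list (y, log axis) for the thresholded peaks found in both; each point is a peak, blue for chromosome 4 or centromere-proximal segments and grey for other regions. Across 3470 peaks Spearman's rho was 0.734, and the 2 axes are not on a shared scale.

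Peaks lay at promoters more often than shifted peaks did. The summit lay within 500 bp of an annotated TSS for 1917 of 3535 peaks (54.2%, Wilson 95% interval 52.6 to 55.9%), against a mean of 13.5% for shifted peaks (range 11.7 to 15.6%, n = 1000 shifts, two-sided p = 0.001, the smallest possible). The share was 41.6% at a distance of 200 bp and 46.8% with 1 TSS per gene, so whether promoters hold a majority depends on the definition. The median distance of those summits to the TSS was 98 bp. Introns held 28.0% of summits (39.7% of shifted ones), intergenic sequence 14.8% (27.0%), coding exons 0.962% (13.9%), 3' UTRs 0.820% (4.498%) and 5' UTRs outside the promoter windows 0.481% (0.789%). Promoter peaks were also stronger, with a median signal of 211.6 against 170.1 for the other 1618 peaks (permutation test, 100000 resamples, p = 1.00e-05, the smallest possible). These p-values describe the placement of this peak set, since peaks are not samples. Against the next-ranked peaks of the pooled list the promoter share was 54.2% to 36.4%.

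Chromosome 4 and the centromere-proximal segments of the large arms stood apart. On chromosome 4, a small and largely heterochromatic chromosome, 61 of 140 promoters were bound (43.6%, Wilson 95% interval 35.6 to 51.9%), against 10.6% elsewhere (odds ratio 6.48, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 8 region classes, adjusted p = 1.67e-22). In the centromere-proximal segments 129 of 418 were bound (30.9%, 26.6 to 35.5%), against 10.4% elsewhere (odds ratio 3.84, exact adjusted p = 2.07e-28). The shares on 2L, 2R, 3L, 3R and X were 10.7, 10.7, 10.9, 10.9 and 10.3%, and none of these arms passed the test. No promoter of the 112 on Y was bound (exact adjusted p = 1.20e-05), which allows a share of up to 2.68%. The Y is poor in unique sequence, so reads placed there may be few for that reason alone, and mappability was not measured here.

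Signal rose with these regions as well. The median signal of promoter peaks was 1474 on chromosome 4 and 1443 in the centromere-proximal segments, against 189.6 to 224.2 on the large arms. Of the 100 strongest peaks, 21 lay on chromosome 4, 50 in centromere-proximal segments and 90 at promoters. Chromosome 4 makes up 1.01% of the sequence and the segments 13.6%. Of all thresholded peaks, 3.03% lay on chromosome 4 and 10.6% in the segments. Chromosome 4 held 79.4 peaks per Mb and the segments 20.7, against 23.9 to 28.1 on the large arms. With the 500 highest peaks alone, a setting chosen after seeing the data, 5 classes passed the test: promoters on X (odds ratio 0.468, exact adjusted p = 1.59e-05) and 3R (0.708, 0.0149) were bound less often and those on 2R (1.40, 0.00968) more often, while Y did not pass (0.246). The arms here include their centromere-proximal segments. With those left out, 2R (odds ratio 1.00, exact adjusted p = 1.00) and 3R (0.838) did not pass, and X (0.631, 0.0397) and chromosome 4 did. X also passed at a promoter distance of 200 bp (odds ratio 0.784, exact adjusted p = 0.00401).

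**Figure D2:**
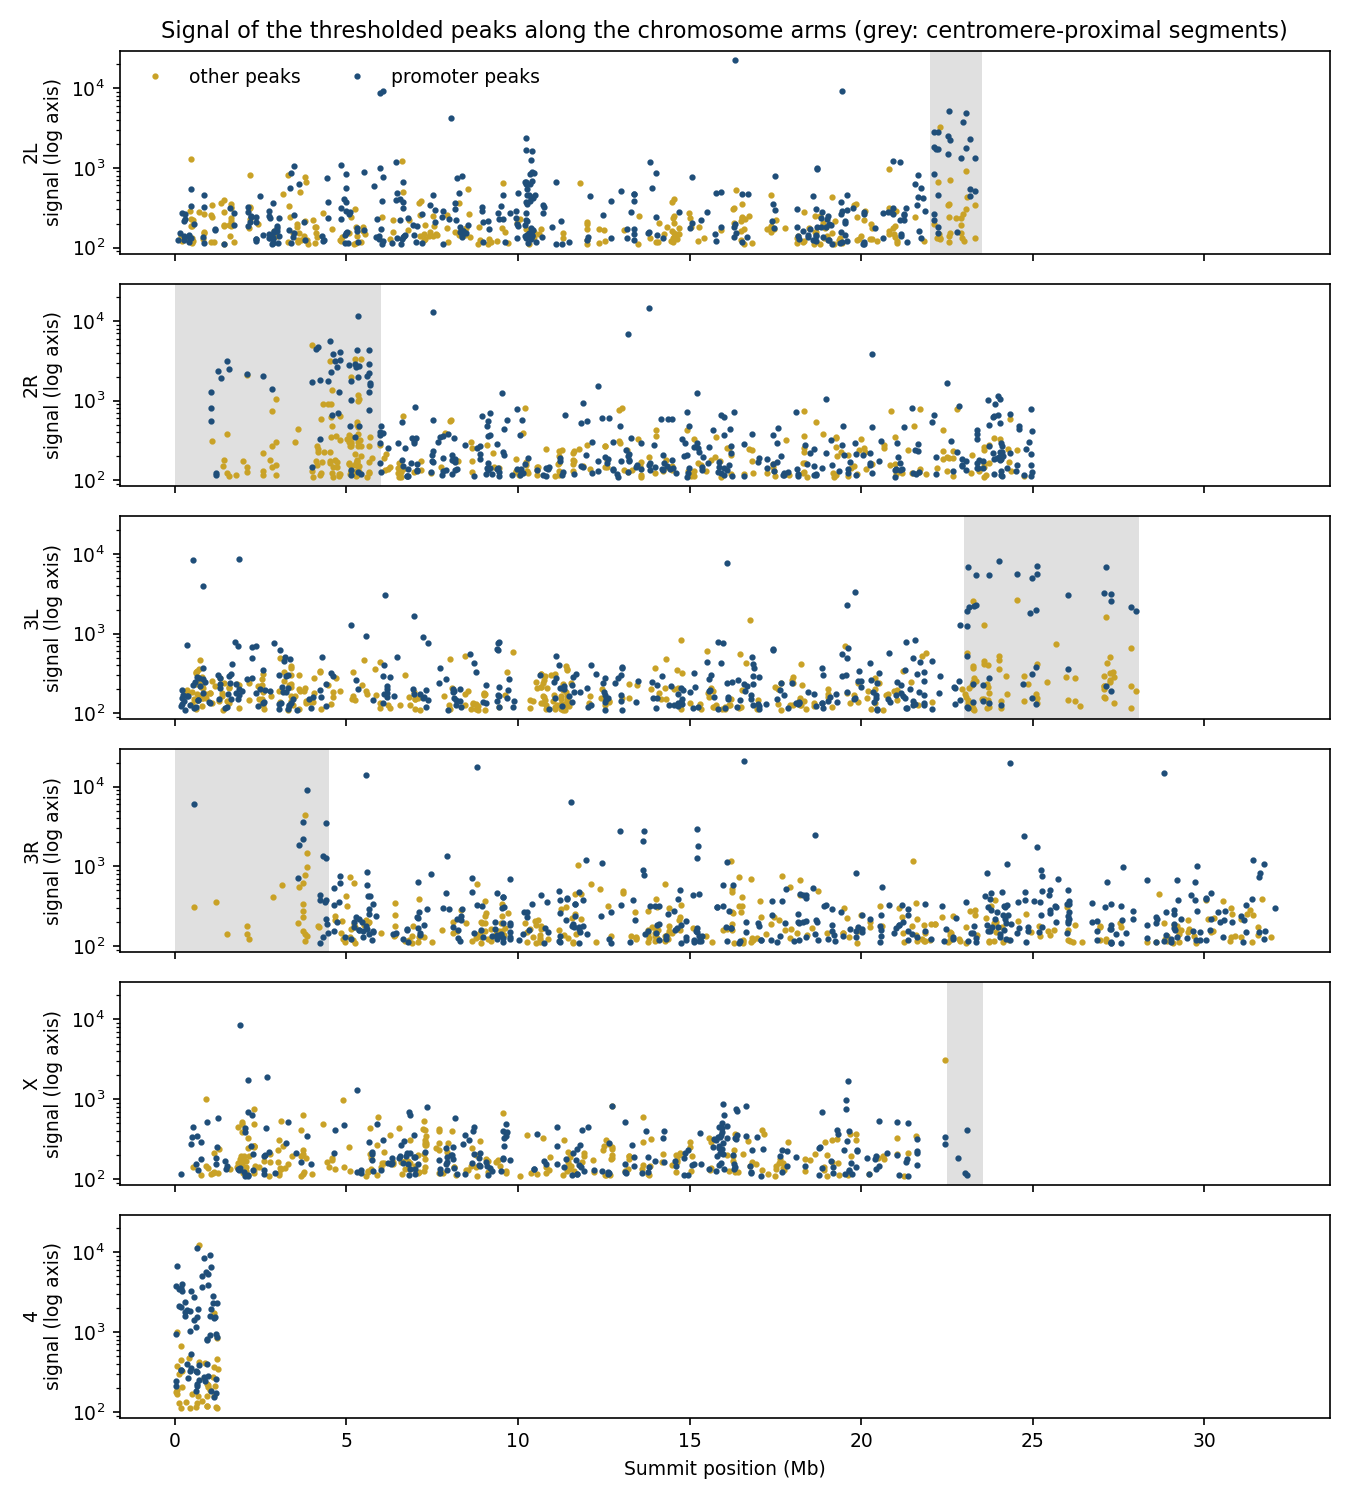
Signal of each thresholded peak (y, log axis) by summit position in Mb (x) on the 6 arms, blue for promoter peaks and yellow for other peaks, with centromere-proximal segments in grey. Promoter peaks had a median signal of 1474 on chromosome 4 and 1443 in the grey segments, against 189.6 to 224.2 on the large arms.

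**Figure D3:**
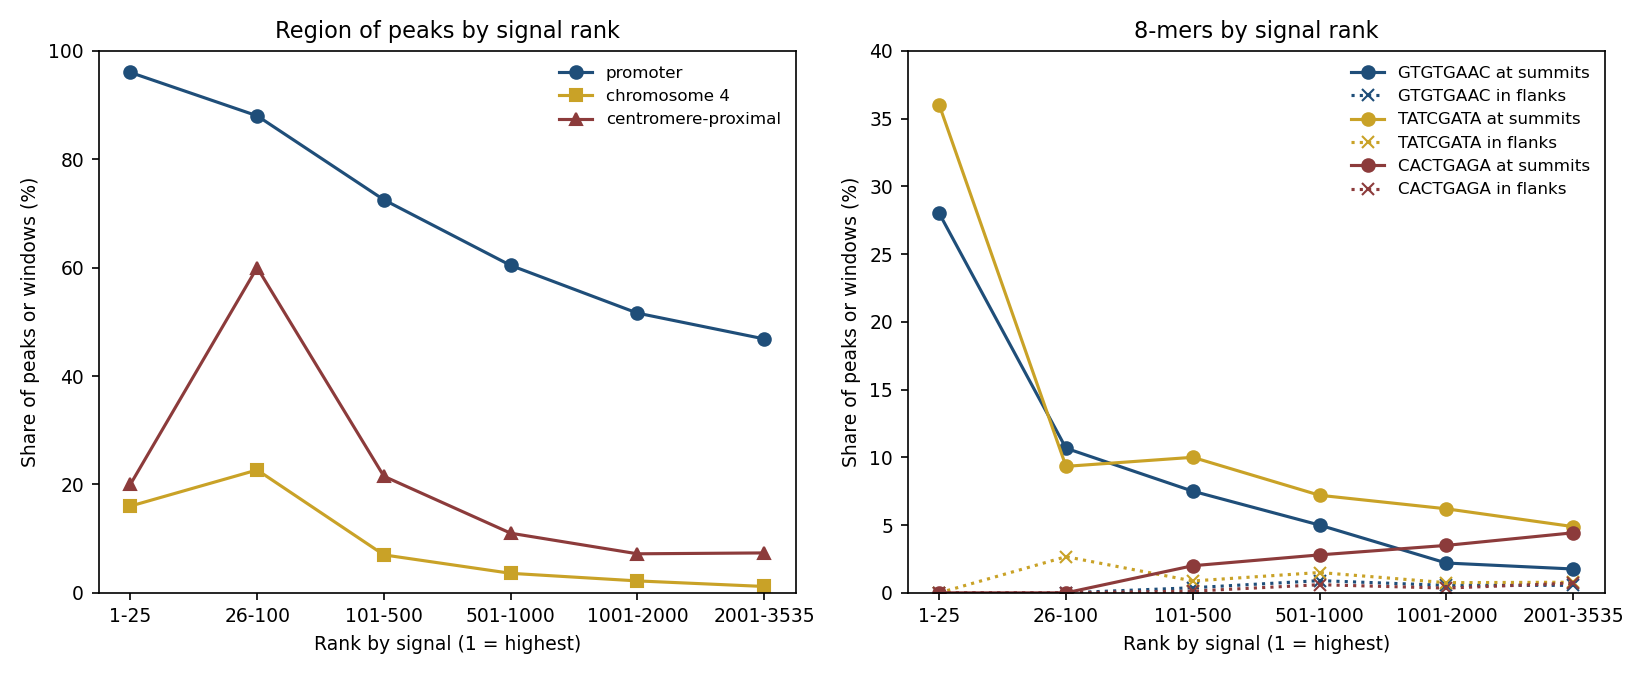
Share of thresholded peaks in each rank bin (x, rank 1 is the highest signal) that lay at promoters, on chromosome 4 or in centromere-proximal segments (left), and the share of summit windows and flanks with each 8-mer (right). Promoter peaks made up 96.0% of ranks 1 to 25 and 46.8% of ranks 2001 to 3535.

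Genes of the cytosolic ribosome were the most often bound of 28 gene lists. A thresholded summit lay within 500 bp of a TSS for 68 of 93 cytosolic ribosomal protein genes (73.1%, Wilson 95% interval 63.3 to 81.1%), against 16.5% of other protein-coding genes (odds ratio 13.8, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.22e-31). RpS3A had the strongest peak of them (signal 6673), followed by RpL38 (5527), RpL36A (4258) and RpL5 (2540). RpS3A lies on chromosome 4, and RpL38 and RpL5 lie in centromere-proximal segments, where promoter peaks had more signal in general. With genes of both regions left out, a setting chosen after seeing the data, 62 of 87 ribosomal protein genes were bound (71.3 against 15.7%). The general transcription machinery had 26 of 63 genes bound (41.3%, exact adjusted p = 1.59e-05), among them the Mediator subunits MED21 (5650), MED26 (5119), MED8 (3901) and MED31 (530.2). MED26 lies on chromosome 4 and MED21 in a centromere-proximal segment. The MED8 peak lies closer to CG8929 (31 against 433 bp) and the MED31 peak to CG9775 (38 against 163 bp). Across all lists, 24 of the 85 entries named lie closer to a TSS of another gene, so their peaks cannot be assigned to the member alone.

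The Polycomb group, insulator and architectural proteins, the Trithorax group and oxidative phosphorylation also had more genes bound than background. The Polycomb group had 11 of 22 genes bound (50%, exact adjusted p = 0.00123), with sxc (signal 4367), ph-p (1748), pho (1560) and Asx (597.4) at the top. Insulator and architectural proteins had 10 of 21 (47.6%, exact adjusted p = 0.00330), led by vtd (6858), Nipped-B (2665), Clamp (1732) and Chro (1269). The Trithorax group had 9 of 19 (47.4%, exact adjusted p = 0.00555), led by trr (8540), Set1 (1951), brm (756.1) and mor (592.1). Oxidative phosphorylation had 24 of 84 (28.6%, exact adjusted p = 0.0180), led by ND-51 (9251), UQCR-11 (6946), ND-AGGG (4906) and ND-49 (2760). That last call was lost without replicate 1 (exact adjusted p = 0.0644), without replicate 2 (0.0781) and in 4 other settings, over a range of 0.00586 to 0.903. These settings include the one without chromosome 4 and the centromere-proximal segments (exact adjusted p = 0.133). Of the genes named here, sxc, pho, vtd, Nipped-B, Clamp, Set1, UQCR-11, ND-AGGG and ND-49 lie in those regions, where promoter peaks had more signal in general. With only genes that had a pooled-list peak as background, the calls of the Trithorax group (0.463; range over settings 0.00482 to 0.463) and of insulator proteins (0.228; range 0.00169 to 0.228) were lost as well, and Trithorax also at 200 bp (0.0527) and with each peak given to its nearest gene only (0.166). The trr peak lies closer to mRpL16 (81 against 225 bp) and the ND-51 peak to CG13994 (63 against 169 bp).

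Chemoreceptor, cuticle and digestive genes, tRNA and small RNA genes and histones were bound less often than background. The counts were 1 of 179 chemoreceptors (0.559%, exact adjusted p = 2.92e-12), of which the bound gene was Ir60b (signal 131.3, closer to Letm1), 0 of 121 cuticle protein genes (exact adjusted p = 2.33e-09) and 0 of 33 digestive enzymes and larval serum proteins (exact adjusted p = 0.0101), which allow shares of up to 2.48 and 9.09%. The digestive call was lost without replicate 1 (exact adjusted p = 0.0715), at 200 bp (0.0616), with the nearest gene only (0.0782) and with the 1767 strongest peaks (0.179), over a range of 0.00489 to 0.179. tRNA genes had 7 of 295 bound (2.37%, exact adjusted p = 7.49e-11), with the highest signal at tRNA:Tyr-GTA-1-8 (477.6), tRNA:Gly-GCC-1-9 and tRNA:Trp-CCA-2-2, which share a peak closer to CG30122 (249.4), and tRNA:Phe-GAA-1-2 (195.0), whose peak lies closer to RpL17 (68 against 237 bp). Small nuclear and nucleolar RNA genes had 13 of 306 (4.25%, exact adjusted p = 1.03e-07), led by snoRNA:Psi18S-1086 (3985), snoRNA:Me18S-G1358c (2526), snoRNA:U49:66Da (548.2) and snoRNA:Or-CD11a (509.1). All 4 peaks lie closer to another gene, namely Sf3b3 (77 against 253 bp) and the ribosomal protein genes RpL15 (82 against 210 bp), RpL14 (29 against 496 bp) and RpL28 (30 against 449 bp), and with the nearest gene only 2 of 306 were bound. Histones had 3 of 115 (2.61%, exact adjusted p = 1.01e-05), namely His2Av (206.6, closer to ball), His4r (167.0, closer to put) and His3.3A (114.5). Most histone genes and many tRNA genes are near-identical repeats, where reads cannot be placed uniquely. Neighbouring members of a list, such as the tRNA genes that share a peak, were counted as independent genes. The p-values of lists with clustered members may therefore be too small. With only genes that had a pooled-list peak as background, 5 of the 25 lists that could be tested passed, histones and digestive enzymes had too few members left to test, and tRNA genes (exact adjusted p = 0.146; range over settings 1.04e-11 to 0.146) and small RNA genes (0.605; range 1.69e-10 to 0.605) did not. Small RNA genes also did not pass at 1000 bp (14.7 against 16.8%, exact adjusted p = 0.540).

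No call was made for the other 16 lists. Mitochondrial ribosomal proteins had 20 of 73 bound (exact adjusted p = 0.0571), with mRpL16 (signal 8540), mRpS5 (5541), mRpS10 (1281) and mRpL41 (1231); without replicate 1 (0.00664) and with 1 TSS per gene (0.0169) they passed (range over settings 0.00664 to 0.672). ZAD zinc finger proteins, the family of CG17802, had 16 of 70 (exact adjusted p = 0.346), with CG10147 (501.6), wek (483.3), Sry-delta (391.4) and CG4820 (378.1). Heterochromatin proteins had 8 of 28 (exact adjusted p = 0.231), with prod (220.4), HP1b (165.5), JIL-1 (156.3) and Su(var)3-9 (135.8); without replicate 2 (0.0402) and at 200 bp (0.0459) they passed (range 0.0402 to 1). The piRNA pathway had 5 of 30 (exact adjusted p = 1), with vas (764.9), papi (238.9), AGO3 (229.2) and cuff (148.0), and germ plasm and germline genes 4 of 14 (0.385), with vas, bgcn (639.8), orb (177.1) and gcl (112.2). The proteasome had 6 of 32 (0.842), with Prosbeta1 (368.1), Prosalpha2 (235.8), Rpn3 (198.3) and Rpn5 (151.3). Cell cycle and replication had 8 of 32 (0.346), with Cdk1 (428.4), CycD (359.4), Dp (213.4) and dpa (207.3), and heat shock 5 of 26 (0.842), with Hsc70-4 (1785), Hsp27 (632.4), Hsp83 (456.6) and Hsc70-5 (166.6).

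The lists of patterning and tissue genes were among those not called. Segmentation genes had 1 of 24 bound (bcd, signal 166.0, exact adjusted p = 0.214), dorsoventral and mesoderm genes 1 of 20 (tin, 246.1, exact adjusted p = 0.346), and homeotic genes 2 of 10 (exd, 134.0, and Dfd, 111.5, exact adjusted p = 0.793). Notch pathway and E(spl) genes had 5 of 19 (exact adjusted p = 0.468), with H (554.6), E(spl)m7-HLH (239.9), numb (227.9) and E(spl)m3-HLH (206.4). Ecdysone synthesis and response had 4 of 22 (exact adjusted p = 0.842), namely usp (387.3), Hr39 (266.2), Eip75B (238.0) and Npc1a (138.3). Neural genes had 2 of 20 (elav, 453.0, and scrt, 115.3, exact adjusted p = 0.682), and muscle structural genes 2 of 21 (sls, 265.9, and Tm1, 115.5, exact adjusted p = 0.682). Among the members named here and in the preceding lists, peaks lay closer to another gene for CG10147 (Bulli), CG4820 (RpS25), cuff (CG13185), orb (Cdc16), Prosbeta1 (Rrp42), Rpn5 (Hat1), Hsc70-5 (CG8531), exd (CG46312 and eIF5), E(spl)m3-HLH (lncRNA:CR43644) and Npc1a (Prosalpha6). The single hit among 20 eggshell and yolk genes (exact adjusted p = 0.346) was Cp190 (453.7), an insulator protein that the list's name pattern picked up.

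**Figure D4:**
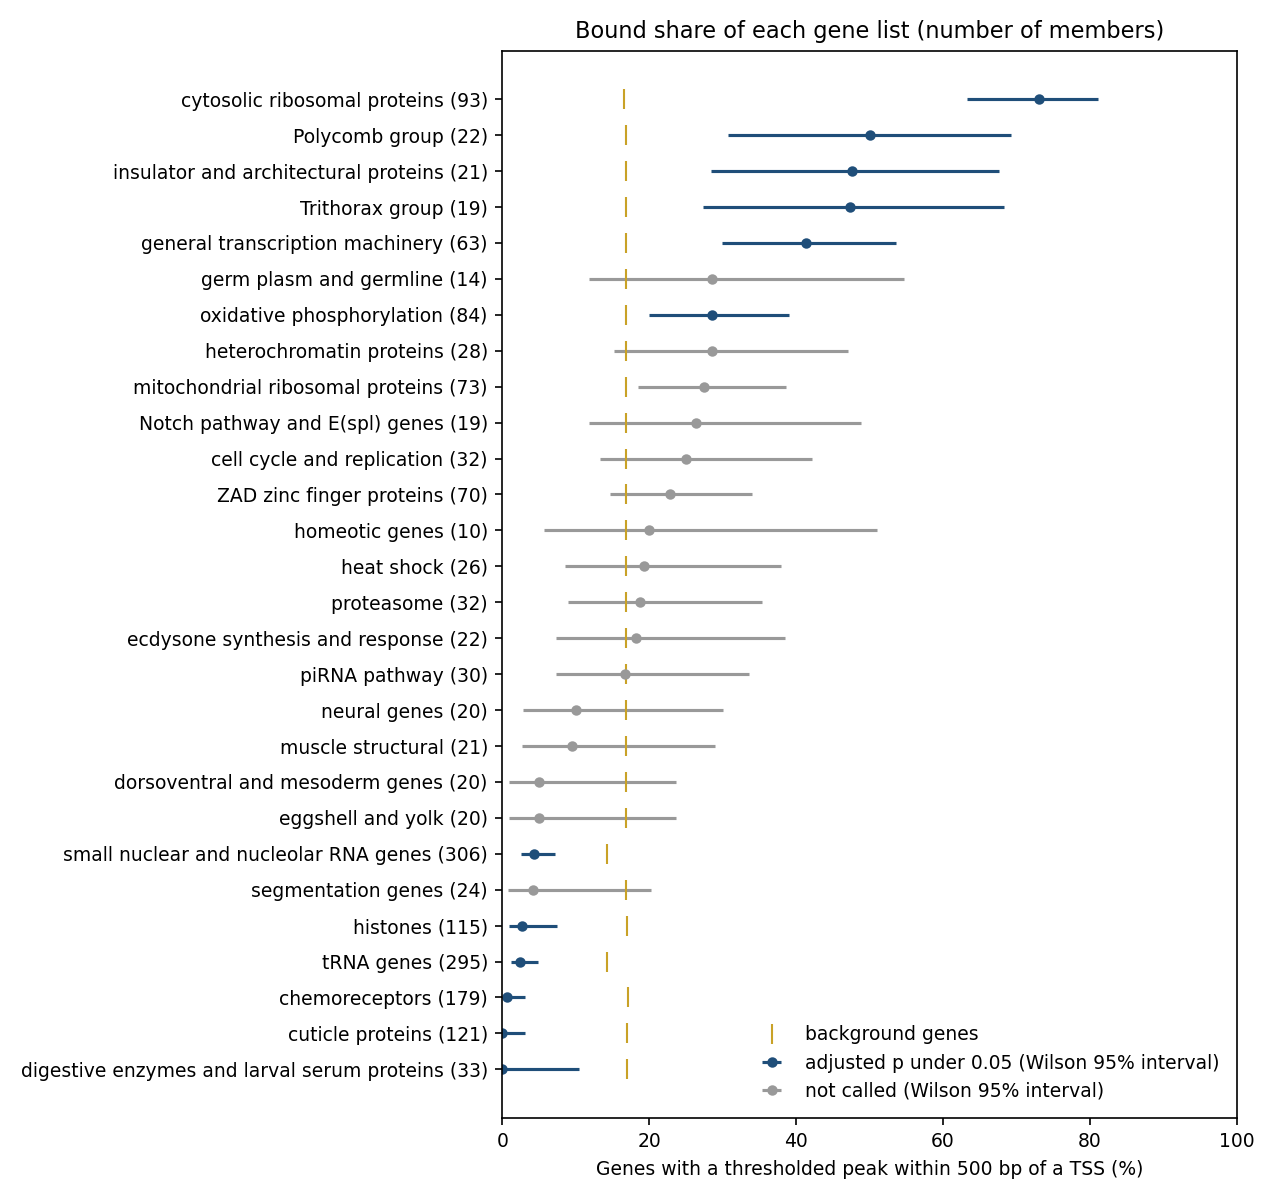
Share of genes in each list with a thresholded summit within 500 bp of a TSS (x, percent), with the number of members beside each name; dots are list shares with Wilson 95% intervals, blue where the adjusted p was under 0.05, and ticks are the background genes. Cytosolic ribosomal proteins stood at 73.1% against a background of 16.5%.

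Of 16 fixed motifs, 14 differed in frequency between summits and flanks. The DRE, TATCGATA, the site of the DREF factor, lay within 100 bp of 6.48% of summits and in 0.919% of flanking windows 500 bp away (odds ratio 7.47, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 16 motifs, adjusted p = 6.80e-56). Paired CGATA sites, bound by BEAF-32, were at 8.46 against 1.75% (exact adjusted p = 1.57e-56), and the Motif 1 sequence GGTCACAC, bound by M1BP, at 3.82 against 0.750% (exact adjusted p = 1.56e-26). Ohler motif 7 (3.96 against 1.63%), Ohler motif 6 (1.53 against 0.523%), the ZIPIC core (2.999 against 0.990%), the CTCF core (1.16 against 0.580%), the Su(Hw) core (1.19 against 0.750%) and TATA (10.3 against 7.96%) were also higher, with adjusted p of 3.51e-12, 1.06e-06, 1.17e-12, 0.00362, 0.0325 and 1.20e-04. Lower at summits were CA repeats (3.65 against 6.25%), GAGA (3.65 against 4.61%), the CLAMP GA repeat (0.424 against 0.834%), the Zelda site (0.764 against 1.26%) and the Initiator (15.9 against 17.8%), with adjusted p of 2.67e-08, 0.0276, 0.0273, 0.0276 and 0.0273. With windows of 250 bp, GAGA (12.3 against 8.39%, exact adjusted p = 6.83e-10), CA repeats (12.2 against 10.6%, 0.0305) and the CLAMP repeat (2.63 against 1.95%, 0.0380) were instead higher at summits. The flanks of that setting also lay farther from the summit, so the wider window alone cannot be credited with the change. Against unbound promoters TATA was at 10.4 against 11.7% (exact adjusted p = 0.216) and the Initiator at 15.7 against 25.7% (1.14e-13). The E-boxes CAGCTG (exact adjusted p = 0.889) and CACGTG (0.6001) were not called. Without replicate 2, 8 motifs passed in place of 14: CA repeats (exact adjusted p = 0.106), GAGA (0.639), the CLAMP repeat (0.639), the Initiator (0.351), TATA (0.164) and Su(Hw) (0.283) did not, and without replicate 1 the CLAMP repeat (0.0988) and CTCF (0.0791) did not. Against next-ranked peaks 3 passed (DRE, paired CGATA and CA repeats). The calls of Su(Hw), TATA, Zelda, the Initiator, GAGA and the CLAMP repeat were lost in other settings too, with adjusted p of up to 0.912, 0.216, 0.382, 0.351, 0.639 and 0.639.

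Unbiased 8-mers gave further sequences. The 5 found on 2L and 3L were retested on 2R, 3R, X and 4, and all passed Fisher's exact test with Benjamini-Hochberg adjustment. TATCGATA was at 7.37% of summits against 1.06% of flanks (exact adjusted p = 1.05e-38), GTGTGAAC at 3.33 against 0.516% (3.60e-17), CACTGAGA at 3.19 against 0.657% (9.09e-14), ATTTTTAA at 8.35 against 4.95% (1.99e-07) and AAATAATA at 6.76 against 4.83% (0.00195). ATTTTTAA and AAATAATA hold only A and T, with odds ratios of 1.75 and 1.43, and base composition was not controlled for. With the 500 highest peaks ATTTTTAA did not pass (exact adjusted p = 0.0599). GTGTGAAC was more frequent in strong peaks, at 5.04% of the 1767 strongest and 1.70% of the 1768 weaker peaks (exact adjusted p = 6.69e-08), as was TATCGATA, at 8.09 and 4.86% (1.41e-04). On the retest arms, of occurrences within 500 bp of a summit, 45.7% lay within 50 bp for GTGTGAAC, 28.9% for TATCGATA and 21.0% for CACTGAGA, where an even spread would give 10.2%. CACTGAGA was at 2.89% of the stronger and 4.19% of the weaker peaks (exact adjusted p = 0.0447), and 30.4% of its peaks were at promoters, against 86.5% for TATCGATA and 62.2% for GTGTGAAC. Discovery from replicate 1's list alone gave 5 called 8-mers of which 1 was shared with these, and GTGTGAAC was not among them. The Motif 1 sequence GGTCACAC was (4.64 against 1.01%, exact adjusted p = 1.05e-18). Its reverse complement GTGTGACC shares GTGTGA with GTGTGAAC, and 8-mers sharing 5 bases in a row were not both picked. GTGTGAAC could therefore not be picked after GGTCACAC. CACTGAGA could likewise not be picked after CAACACTG, another 8-mer from replicate 1's list, which shares CACTG with it. The absence of GTGTGAAC and CACTGAGA does not show that replicate 1 lacks them. With the next-ranked peaks as control, discovery gave 5 other 8-mers, of which 0 were called. GTGTGAAC was not tested against those peaks. TATCGATA, as the DRE among the fixed motifs, passed against them (6.48 against 3.51%, exact adjusted p = 1.72e-07). Among 6-mers, ACACTG was at 21.5% of summits and 7.63% of flanks (exact adjusted p = 2.06e-53).

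The number of thresholded peaks around the tagged gene did not pass the test. Within Nnk (3R:17803225-17805249, minus strand) and 20 kb to each side, 3 thresholded peaks were found, against a mean of 1.57 in n = 1000 random windows centred on TSSs of 3R (p = 0.505). The strongest (3R:17798295-17798464, signal 516.6, rank 440) was 67 bp from a TSS of CG7379. Replicate 2's own list held 22 peaks there against 11.3 (n = 1000 windows, unadjusted p = 0.042), replicate 1's 18 against 12.1 (0.276) and the pooled list 20 against 11.5 (0.128). The other 2 thresholded peaks were nearest to CG43102, with signals of 192.6 and 157.8. With 10 kb to each side, the pooled list held 14 peaks against 6.27 in random windows (n = 1000 windows, unadjusted p = 0.034). Replicate 2's list held 13 against 6.09 (0.096), replicate 1's 10 against 6.65 (0.362) and the thresholded set 2 against 0.857 (0.462). No thresholded summit lay in the Nnk gene; the pooled list placed one there with a signal of 40.1 and rank 20504, against a list floor of 33.7, and replicate 1's list one with a signal of 30.1 and rank 4463, against a floor of 14.7.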

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

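The settings with the 500 highest peaks, without chromosome 4 and the centromere-proximal segments, and with the pooled list at the locus were chosen after seeing the data. No paired analysis was possible because there is 1 group. Replicate agreement, the promoter share, the shares bound on chromosome 4 and in centromere-proximal segments, and the signal difference at promoters kept their direction and their side of the threshold in every alternative tried. Counts that moved by over 1.5 times were as follows. Gene lists called fell from 12 to 5 with genes that had a pooled-list peak as background, a smaller set in which 25 of 28 lists and 10 of the 12 could be tested. Fixed motifs fell from 14 to 3 against next-ranked peaks and to 8 without replicate 2 (12 without replicate 1, a smaller move). Called 8-mers fell from 5 to 0 against next-ranked peaks, where discovery gave 5 other 8-mers and the main 5 were not retested. They fell to 2 with the 500 highest peaks, which also raised the region classes called from 3 to 5 (2 with the centromere-proximal promoters left out). The cause was not tested for these. Each replicate's list alone still gave 5 called 8-mers, but without replicate 2 only 1 was shared with the main 5. The rule against shared bases barred GTGTGAAC and CACTGAGA in that setting, so this count is partly set by the rule. At the CG17802 locus the 50 kb window held 3 peaks, below its random mean of 3.30 (n = 1000 random windows, p = 1).

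Differences from background (percentage points) that turned their sign follow; no list was called with its sign turned. With the 1767 strongest peaks they were -0.292 for the proteasome, -6.11 for heterochromatin proteins, 0.334 for the piRNA pathway and -9.67 for homeotic genes. Over each replicate left out, with the value of the other replicate given too, they were -1.22 and -0.842 for the proteasome, -6.84 and -6.47 for homeotic genes, -2.56 and 19.3 for heterochromatin proteins, and -11.9 and 3.54 for dorsoventral and mesoderm genes, without replicates 1 and 2 in that order; 19.3 and -11.9 did not turn, and the former was called. At 200 bp homeotic genes were at -2.31 and Notch pathway genes at -1.78. At 1000 bp the proteasome was at -0.477, the piRNA pathway at 0.776 and ecdysone genes at -1.05. With 1 TSS per gene ecdysone genes were at -1.58, and with the nearest gene only homeotic genes were at -1.98. With pooled-list genes as background the values were -10.9 for the proteasome, -3.92 for the cell cycle, -1.13 for ZAD proteins, -2.58 for heterochromatin proteins, -2.57 for homeotic genes and -5.14 for ecdysone genes.

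Among motifs, windows of 250 bp turned GAGA (3.95), CA repeats (1.53) and the CLAMP GA repeat (0.679) from lower to higher with a call, and the Initiator (1.10) and the E-box CACGTG (0.580) without one. Without replicates 1 and 2, in that order, GAGA was at -1.23 and 0.226, CACGTG at -0.339 and 0.269 and the E-box CAGCTG at -0.424 and 1.36. CAGCTG was also at -0.792 with the 1767 strongest peaks, -0.424 with 50 bp windows and -0.424 against next-ranked peaks, where CACGTG was at 0.424. Against unbound promoters CACGTG was at 0.783 and TATA at -1.30. The depletion of GA and CA repeats therefore depends on the setting of window and flanks, which changed together here. The cause was not tested. Of the other list and motif values under an alternative, 274 stayed on their side of the threshold, 45 lost a call and 5 gained one.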

Other observations

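The test of the input label, the weight matrix, the dense windows, the transposable elements, the counts of strong distal peaks and the ratio for peaks without the element were chosen only after results had been seen. The other tests were written down before their results were seen, but without saying how the sequence element was to be defined; both definitions used here were set later, the matrix values were seen first, and both are given.

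A weight matrix was grown from GTGTGAAC on the 178 peaks of 2L and 3L among the 500 strongest. It had the consensus NNNCCAGTGTGAACNNNNCT from 23 sites. At a score exceeded by 1% of flanks on those arms, it matched 24.2% of ranks 1 to 100 on the arms not used to build it, 13.3% of the ranks from there to 500, 7.89% of ranks 501 to 1000, 5.30% of ranks 1001 to 2000 and 2.92% of ranks 2001 to 3535, against 0.774% of flanks. Its consensus holds CAGTGT, the reverse complement of the 6-mer ACACTG, as do the 8-mer CAACACTG found in replicate 1's list and the 7-mer CAGTGTA, on one strand or the other. The first C and A of CAGTGT lie outside GTGTGAAC, where the letters of the consensus stood at only 54 to 58% in the matrix. Whether these letters add to the 8-mer was not tested.

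Peaks were unevenly spread within arms. The densest window of 250 kb was the centromere-proximal 2R:5250001-5500000, with 37 thresholded peaks, 10 of them at promoters. Outside such segments and chromosome 4, 2L:10250001-10500000 held 28 peaks, 25 of them at promoters (76 promoters in the window), and X:15750001-16000000 held 20, all 20 at promoters (60). In 3L:11250001-11500000 25 peaks were found, 4 of them at promoters (30), and in 3L:500001-750000 24, of which 10 were at promoters (44). The median occupied window held 6. Annotated transposable elements held 1.98% of thresholded summits, against 6.28% of shifted ones. In the pooled list, most of it background, the shares were 1.75 and 6.11%, so the shortfall is not particular to the thresholded peaks. Mappability of these elements was not measured here.

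Promoters on chromosome 4 and in centromere-proximal segments were bound more often, and with more signal, than those elsewhere. The 8-mer GTGTGAAC was 2.51 times as frequent there and its matrix 1.08 times. Few promoters held either: 4.12% there and 1.64% elsewhere for the 8-mer, 5.02 and 4.64% for the matrix. Among promoters without the element the bound odds ratio was still 4.60 (95% interval 3.82 to 5.55) with the 8-mer and 4.497 (3.72 to 5.44) with the matrix. With so few promoters left out this ratio could hardly have changed, so it adds little as a test. The low shares argue against a higher frequency of the element, as defined here, as the whole cause. Weaker sites count as without it and were not tested. More signal per element was seen, with a ratio of median signals of 7.93 with the 8-mer (9 against 65 promoter peaks, permutation p = 0.00131) and 7.57 with the matrix (25 against 123, p = 1.00e-05, the smallest possible), but promoter peaks without the 8-mer had a ratio of 6.90, so this is not particular to the element. A regional bias of coverage or of the control stays open and may contribute: peaks over 1000 bp from a TSS had a ratio of 1.06 (95% bootstrap interval 1.04 to 1.08), which met the bound written beforehand for no bias, but that bound was wrong, because the pooled list ends at a signal floor and a true bias of 1.5 times would itself give a ratio of 0.988. Strong distal peaks were in fact more frequent there, with Fisher's exact odds ratios of 1.55, 6.65 and 34.2 for a signal of at least 100, 500 and 1000 (p = 2.07e-08, 1.20e-12 and 1.93e-10; 31 of 2150 against 37 of 16859 at 500), against 3.42, 16.7 and 46.5 for promoter peaks, so the pattern is not confined to promoters, and the 2 sets were not tested against each other; beyond the sequence element no biological explanation was tested.

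The label that calls the libraries an input control cannot be settled from these lists. In the 500 highest peaks of each list GTGTGAAC was 23 times (replicate 1, 46 of 500 against 4 of 1000 flanks) and 29.3 times (replicate 2, 44 of 500 against 3 of 1000) as frequent as in flanks, with Fisher's exact p of 1.43e-18 and 1.48e-18. These values met the bound written against input DNA, which was set after results had been seen. The 8-mer had been found in the set made from both lists, so this test is not independent of it. The antibody field of both libraries names CG17802. Open chromatin could place summits on promoter sequences in input DNA too, and no control track was analysed here, so antibody enrichment and open chromatin cannot be told apart.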
